A study of Mus musculus with 6 samples.

How the data were processed

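Small RNA from exosomes, the vesicles of endosomal origin that cells release, was profiled on 6 microRNA (miRNA) arrays. Per the labels' protocols, purchased mouse endothelial cells grew in a medium with 12% fetal bovine serum and were kept for 48 h at 0.9 mM or 3.5 mM inorganic phosphate. Vesicles were then collected from the culture supernatant by differential centrifugation, and RNA was extracted with TRIzol, cleaned on columns and labelled with the dye Hy3. Each phosphate level had 3 arrays. Whether the serum was cleared of its own vesicles, and whether the 3 arrays of a group came from separate cultures, is not given in the sources used here. The p-values therefore measure the spread between these samples, which may be technical.

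The authors deposited spot intensities of a 1-colour array as foreground and as foreground minus local background, per the file headers, for 15840 spots of 3545 probe identifiers. The scanner and the image software are not given in the sources used here. The probes comprised 1118 for mouse miRNAs, 57 for miRNAs of murine gammaherpesvirus and murine cytomegalovirus, 61 spike controls, 23 for other small RNAs, 7 negative controls and 2276 without a name. Most probes had 4 spots. The deposited normalized intensities equalled the median foreground minus background over a probe's spots divided by a factor for each array. That factor was the median over the 691 named miRNA probes that reached 30 units on all 6 arrays, and it lay between 319 and 344.5 units. The scale and direction of these values were found by setting them against the spot values, and the series' own value table held the same numbers. Another 12 intensity columns in the authors' table, over all samples together, repeated foreground and background-subtracted values and were not used. The authors also deposited a fold change (ratio of test over control), a p-value and a false discovery rate for each named miRNA probe. Their p-value matched an equal-variance t-test on the linear normalized intensities for all 1029 probes that had one, within a tolerance of 1e-06.

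From the deposited spot intensities, background was corrected with normexp (offset 50, limma 3.58.1 in R 4.3.3) over all spots, and the spots of a probe were averaged. Arrays were quantile normalized over the mouse and viral miRNA probes, and values were taken to log2. A mouse probe was tested if its mean foreground minus background exceeded the 95th percentile of the viral miRNA probes on at least 3 of the 6 arrays. This threshold lay between 1627 and 3233 units and left 129 of 1118 mouse probes for testing. Saturated spots were kept, and among mouse probes only miR-143-3p had any, on 2 of its 4 spots in normal phosphate replicate 3 and 1 of 4 in high phosphate replicate 2. Probes were fitted with limma's lmFit and eBayes, high minus normal phosphate, 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. No batch, slide or scan information was given in the sources used here, so none entered the fit.

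Before the data were examined, 14 lists of miRNAs were fixed: endothelial, reported inhibitors and reported promoters of vascular calcification, inflammation and NF-kB, p53 with hypoxia and senescence, the let-7 family, the miR-17-92 and paralogous clusters, the Dlk1-Dio3 imprinted cluster, the Sfmbt2 intronic cluster, and markers of muscle, red cells and serum, leukocytes, epithelium and neurons. Lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. The named probes were also fixed by a rule beforehand. It took up to 10 probes in each direction that passed the test, filled with the smallest unadjusted p where fewer passed, per list the 2 members with the smallest p and the 2 with the highest mean, and both arms of miR-126a and miR-670. This gave 51 probes, of which 50 were tested. Names are those of the array's design, and 4 tested probes carry several miRNA names. Single values per array were compared with 2-sided exact permutation tests, whose smallest possible p with 3 against 3 arrays is 0.1.

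The limma fit was tested on simulated data, in 100 draws for the 129 probes of the comparison of high with normal phosphate. Errors were independent, at the probes' own means, with variances that limma had moderated toward a common value. Each draw changed 10 probes by 1.5-fold, 10 by 2-fold and 10 by 4-fold together. Of these, 17.2% were recovered at 1.5-fold, 67.6% at 2-fold and 97.7% at 4-fold. Changing many probes at once eases the adjustment, so these shares do not give the recovery of a few changed probes. Among all calls, 4.45% were unchanged probes. The number of arrays limits the precision: the 95% interval of a log2 difference extended a median of 0.61 to either side, a factor of 1.53. Alternatives covered the background correction, the normalization between arrays, the deposited values, the filter, the averaging of spots, the variance model, array weights, an equal-variance t-test, the replicate number as a block and the omission of each array. Beyond counts of their brightness, the unnamed probes were not analysed here, and neither were coordinates of miRNA genes.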

Results

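Exosomes from the supernatant of mouse endothelial cells, the cells that line blood vessels, were compared after 48 h at 0.9 mM (normal) or 3.5 mM (high) inorganic phosphate, with 3 arrays per group. The series addresses arterial calcification in end-stage kidney disease, in which blood phosphate is raised, and asks which miRNAs the vesicles carry at each phosphate level. Between 97 and 147 of 1118 mouse miRNA probes per array exceeded the threshold set by probes for viral miRNAs, which the mouse genome does not encode. The median signal of the 129 tested probes was 5592 ± 209 units (SD, n = 3) in normal and 5120 ± 613 units (SD, n = 3) in high phosphate.

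Arrays of both groups gave signal on probes for miRNAs of the vessel wall. The endothelial miR-126a-3p, which is encoded within the gene Egfl7, measured 8210 ± 1597 units (SD, n = 3) in normal and 5474 ± 774 units (SD, n = 3) in high phosphate, and miR-143-3p, known from smooth muscle, measured 51756 ± 9361 and 37766 ± 6610 units (SD, n = 3) before scaling. Signal was also present for the red cell miRNA miR-451a, at 41845 ± 5913 and 32471 ± 6499 units (SD, n = 3), and for the liver miRNA miR-122-5p, at 19411 ± 5967 and 12242 ± 3227 units (SD, n = 3). The muscle miR-206-3p averaged 34863 and 28345 units and the epithelial miR-183-5p 39817 and 33902 units. A probe for a gammaherpesvirus miRNA, mghv-miR-M1-10-3p, averaged 11209 and 11703 units, above miR-126a-3p. Signal alone therefore does not show that a miRNA was in vesicles of the endothelial cells. The mean number of mouse probes above the threshold was 117 ± 17.8 (SD, n = 3) in normal and 125 ± 21 (SD, n = 3) in high phosphate, a difference of 8 (2-sided exact permutation p = 0.7). It depended on the threshold, with 30.3 more probes in high phosphate at a fixed 50 units and 48.7 more above the Empty spots, a threshold chosen after seeing the data (2-sided exact permutation p = 0.2 for each).

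No mouse miRNA passed the test between the phosphate levels. Of 129 tested probes, 0 passed limma with Benjamini-Hochberg adjustment, and 9 had an unadjusted p under 0.05, where 6.45 are expected by chance. The same fit without limma's moderation of the variance called 0 after adjustment and 5 before it. The lowest adjusted p in limma was 0.453. Of the 9, 7 had a higher and 2 a lower mean in high phosphate. All 3 arrays of a group lay on the same side of the other group for 13 probes, against 12.9 (10%) expected by chance.

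The probe with the smallest p was miR-1957a, with a log2 difference of 0.96 (SE 0.27), or 1.94-fold with a 95% interval from 1.26 to 3.00 (limma, Benjamini-Hochberg adjusted p = 0.453). It measured 15274 ± 2409 units (SD, n = 3) in normal and 23732 ± 3856 units (SD, n = 3) in high phosphate. The log2 difference was 1.02 (SE 0.31) for miR-719, 1.32 (SE 0.41) for miR-216a-3p and 0.57 (SE 0.20) for miR-219b-5p. It was 0.64 (SE 0.25) for miR-878-5p, 1.12 (SE 0.44) for miR-344d-3-5p and 0.71 (SE 0.29) for miR-382-5p of the imprinted Dlk1-Dio3 cluster. The list of 10 with a higher mean was completed by miR-5625-3p at 0.50 (SE 0.23), miR-26a-2-3p at 0.46 (SE 0.22) and miR-501-5p at 1.33 (SE 0.66).

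With a lower mean in high phosphate, miR-466i-5p had a log2 difference of -0.80 (SE 0.25, limma Benjamini-Hochberg adjusted p = 0.453) and miR-19b-3p of the miR-17-92 cluster -0.55 (SE 0.19, limma adjusted p = 0.518). The muscle miRNA miR-1a-3p stood at -0.74 (SE 0.33) and let-7c-5p at -0.79 (SE 0.37). Differences were -0.43 (SE 0.22) for miR-299a-5p, -0.38 (SE 0.21) for miR-92a-3p and -0.55 (SE 0.30) for miR-26b-5p. The probe shared by miR-199a-3p and miR-199b-3p stood at -0.98 (SE 0.55), miR-93-5p at -0.71 (SE 0.43) and miR-3970 at -0.55 (SE 0.35). Leaving out a single array moved the log2 difference by more than a factor of 1.5 for 8 of these 20 probes, and for 36 of all 50 probes named in this text and tested. Small differences exceed such a factor most easily, so the counts do not compare the stability of large and small ones. The probe of miR-199a-3p and miR-199b-3p stood at -0.40 without high phosphate replicate 1, and let-7c-5p at -0.34 without high phosphate replicate 2. Values for miR-93-5p ran from -1.17 without high phosphate replicate 3 to -0.24 without high phosphate replicate 2, and for miR-501-5p from 0.66 without normal phosphate replicate 1 to 2.05 without normal phosphate replicate 2. Scaling to the Hy3 spots, an alternative chosen after seeing the data, gave 4 calls, namely miR-719, miR-216a-3p, miR-1957a and miR-344d-3-5p (limma, lowest adjusted p = 0.0309). The same scaling turned miR-19b-3p to 0.009, miR-299a-5p to 0.003 and miR-92a-3p to 0.019, while the other probes listed with a lower mean stayed negative. Median scaling without a filter, also chosen after seeing the data, gave 5 calls with limma after adjustment, of which miR-501-5p alone was bright enough for the test above. In that fit all 5 had the same SE of 0.38, so the spread of the single probe carried no weight, and the groups overlapped before scaling for miR-501-5p, miR-5104 and miR-411-3p.

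**Figure D1:**
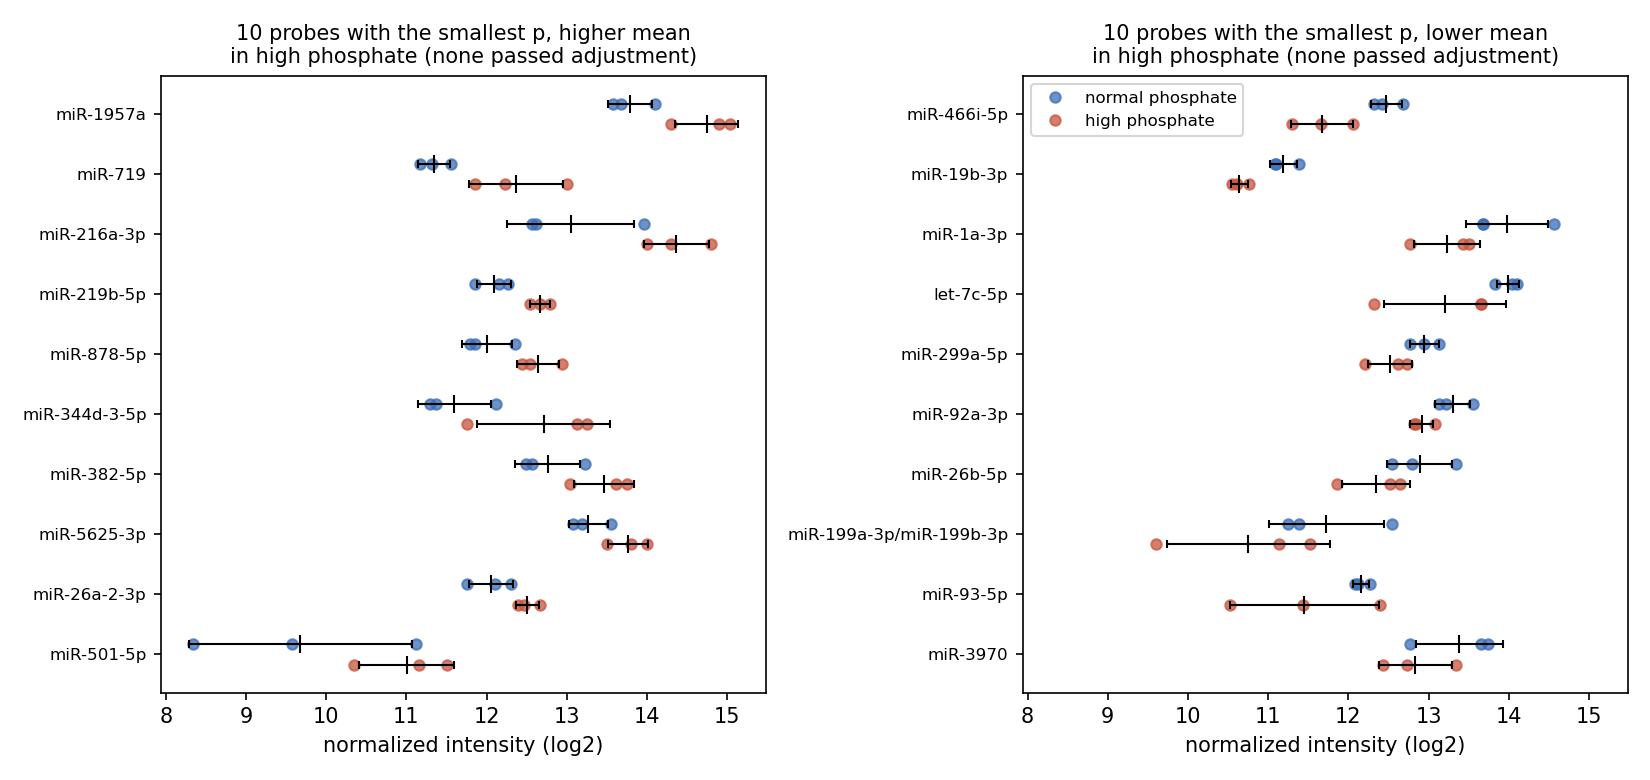
Normalized log2 intensity (horizontal axis) of the 10 probes with the smallest p and a higher mean (left) and the 10 with a lower mean (right) in high phosphate; points are the 3 arrays of each group, and black bars show the mean and SD. No probe passed Benjamini-Hochberg adjustment in limma, and the log2 differences on the left run from 0.46 for miR-26a-2-3p to 1.33 for miR-501-5p.

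Neither arm of miR-126a and miR-670, fixed before the data were examined, passed the test. For miR-126a-3p the log2 difference was -0.30 (SE 0.26), with a 95% interval from -0.90 to 0.31, although before scaling its arrays ran from 6845 to 9967 units in normal and from 4603 to 6084 units in high phosphate, without overlap (2-sided exact permutation p = 0.1, the smallest possible). Leaving out each array in turn moved the log2 difference of miR-126a-3p between -0.46 (without high phosphate replicate 3) and -0.09 (without high phosphate replicate 1). For the opposite arm miR-126a-5p the log2 difference was 0.17 (SE 0.26), with an interval from -0.44 to 0.78, and it became -0.05 without high phosphate replicate 2. The difference for miR-670-5p was -0.05 (SE 0.31). The other arm, miR-670-3p, was below the threshold on all 6 arrays and was not tested. It measured 553 ± 119 units (SD, n = 3) in normal and 856 ± 132 units (SD, n = 3) in high phosphate (2-sided exact permutation p = 0.1, the smallest that 3 against 3 arrays can give). After normalization the groups overlapped, with normal phosphate replicate 2 at a log2 level of 9.507 and high phosphate replicate 2 at 9.498.

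Over all 129 tested probes, 67 had a lower and 62 a higher mean in high phosphate, the base rate for the counts per list. Among miRNAs typical of endothelial cells, 13 were tested and 10 had a lower mean in high phosphate, with a median log2 difference of -0.14 (limma camera, adjusted p = 0.188). The members ranged from miR-221-3p at -0.71 (SE 0.54) to miR-126a-5p at 0.17 (SE 0.26), and miR-10a-5p stood at -0.28 (SE 0.22). Without high phosphate replicate 1, miR-221-3p stood at -0.17. For miR-10b-5p quantile normalization gave a log2 level of 15.40 or 15.52 on every array, since it was among the brightest probes, so its difference of 0.04 (SE 0.18) reflects ranks; it was -0.20 with median scaling and -0.44 without normalization between arrays. All 6 tested members of the reported inhibitors of vascular calcification had a lower mean, among them miR-211-5p at -0.40 (SE 0.26), miR-29a-3p at -0.26 (SE 0.19) and miR-30c-5p at -0.13 (SE 0.20). Another, miR-143-3p, was among the brightest probes and had saturated spots on 2 arrays, so its difference of -0.17 (SE 0.20) reflects ranks; it was -0.45 without normalization between arrays. The median of the 6 was -0.15, and the list did not pass (limma camera, adjusted p = 0.188). Without the filter it passed over 18 members (median -0.20, limma camera, adjusted p = 0.0271), a call lost with an estimated correlation (adjusted p = 0.376). Of the reported promoters, 3 were tested and 2 had a lower mean, with miR-146a-5p at -0.34 (SE 0.33) and miR-182-5p at 0.20 (SE 0.20), and the median was -0.34 (limma camera, adjusted p = 0.608). That median is the value of miR-146a-5p, which ran from -0.61 without normal phosphate replicate 2 to -0.02 without normal phosphate replicate 1.

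The miR-17-92 and paralogous clusters, known for their role in proliferation, had the lowest p of the lists. Of 4 tested members 3 had a lower mean, miR-25-3p stood at 0.13 (SE 0.19), and the median was -0.47 (limma camera, adjusted p = 0.188). The unadjusted camera p of that list was 0.0252. With an estimated correlation the p was 0.0832, and with fry it was 0.00922 before and 0.111 after adjustment. Without the filter, camera passed this list over 14 members (median -0.25, adjusted p = 0.00699), a call lost with an estimated correlation (adjusted p = 0.399). Its median turned to 0.07 with scaling to the spike controls and 0.01 with scaling to the Hy3 spots, both chosen after seeing the data. In the let-7 family, which restrains proliferation, 7 of 9 members had a lower mean, with let-7i-5p at -0.29 (SE 0.29), let-7g-5p at -0.18 (SE 0.21) and let-7a-5p at 0.00 (SE 0.24), and the median was -0.18 (limma camera, adjusted p = 0.188).

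Of 4 tested miRNAs of inflammation and NF-kB signalling, 3 had a lower mean and miR-21a-5p stood at 0.36 (SE 0.25), while miR-146b-5p was at -0.01 (SE 0.23), with a list median of -0.14 (limma camera, adjusted p = 0.746). Of 5 tested miRNAs of p53, hypoxia and senescence, 3 had a lower mean, with miR-107-3p at 0.32 (SE 0.26), miR-192-5p at 0.19 (SE 0.19) and miR-215-5p at -0.23 (SE 0.23), and the median was -0.08 (limma camera, adjusted p = 0.983), which ran from -0.23 to 0.15 when each array was left out in turn. In the Dlk1-Dio3 imprinted cluster 5 of 7 tested members had a higher mean and the median was 0.10 (limma camera, adjusted p = 0.605), which became -0.09 without high phosphate replicate 1. Of the 3 tested members of the Sfmbt2 intronic cluster, 1 passed when adjusted over the list alone, miR-466i-5p, against 0 over all probes tested. The others were miR-669n at 0.04 (SE 0.25) and miR-466f at -0.02 (SE 0.27), and the list did not pass (limma camera, adjusted p = 0.339). Without the filter its 69 probes had a median of 0.04 and passed (limma camera, adjusted p = 0.0329), which an estimated correlation ended (adjusted p = 0.537).

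Markers of other cells were measured to see what else the vesicles could hold. Of the red cell and serum miRNAs, 6 of 7 tested members had a lower mean in high phosphate, with miR-122-5p at -0.38 (SE 0.35), miR-16-5p at -0.28 (SE 0.32) and miR-451a at -0.08 (SE 0.18), and a median of -0.19 (limma camera, adjusted p = 0.305). All 3 tested muscle miRNAs had a lower mean, including miR-206-3p at -0.13 (SE 0.19), with a median of -0.17 (limma camera, adjusted p = 0.188). That median is the value of miR-143-3p, which is also among the calcification inhibitors. Further tested miRNAs belong to several lists, among them miR-92a-3p, miR-146a-5p and miR-221-3p, so the lists are not independent of each other. The 3 tested epithelial miRNAs had a higher mean, with miR-183-5p at 0.08 (SE 0.18) and a median of 0.08 (limma camera, adjusted p = 0.498). The direction of the epithelial median depended on the method, as it was -0.23 without the filter and -0.16 without normalization between arrays. The leukocyte list had 2 tested members, miR-142a-5p at -0.24 (SE 0.28) and miR-181a-5p at -0.13 (SE 0.25), and received no test, and the neuronal list had 0. Without the filter 6 leukocyte probes had a median of -0.20 and passed (limma camera, adjusted p = 0.0329), but not with an estimated correlation (adjusted p = 0.376). Of 12 lists tested, 0 passed camera after Benjamini-Hochberg adjustment and 1 had an unadjusted p under 0.05, and adjusted over the list alone 0 members passed in any list except the Sfmbt2 cluster. With the estimated correlation or with fry, 0 lists passed after adjustment. Leaving out a single array moved the median by more than a factor of 1.5 for 11 of the 12 lists, all but the miR-17-92 and paralogous clusters, and turned the direction of 3, the Dlk1-Dio3, Sfmbt2 and p53 lists. Small medians exceed such a factor most easily, and the miR-17-92 median was the largest in size. On the log2 scale it still ran from -0.53 to -0.35, a wider span than that of the epithelial list, from 0.06 to 0.13.

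**Figure D2:**
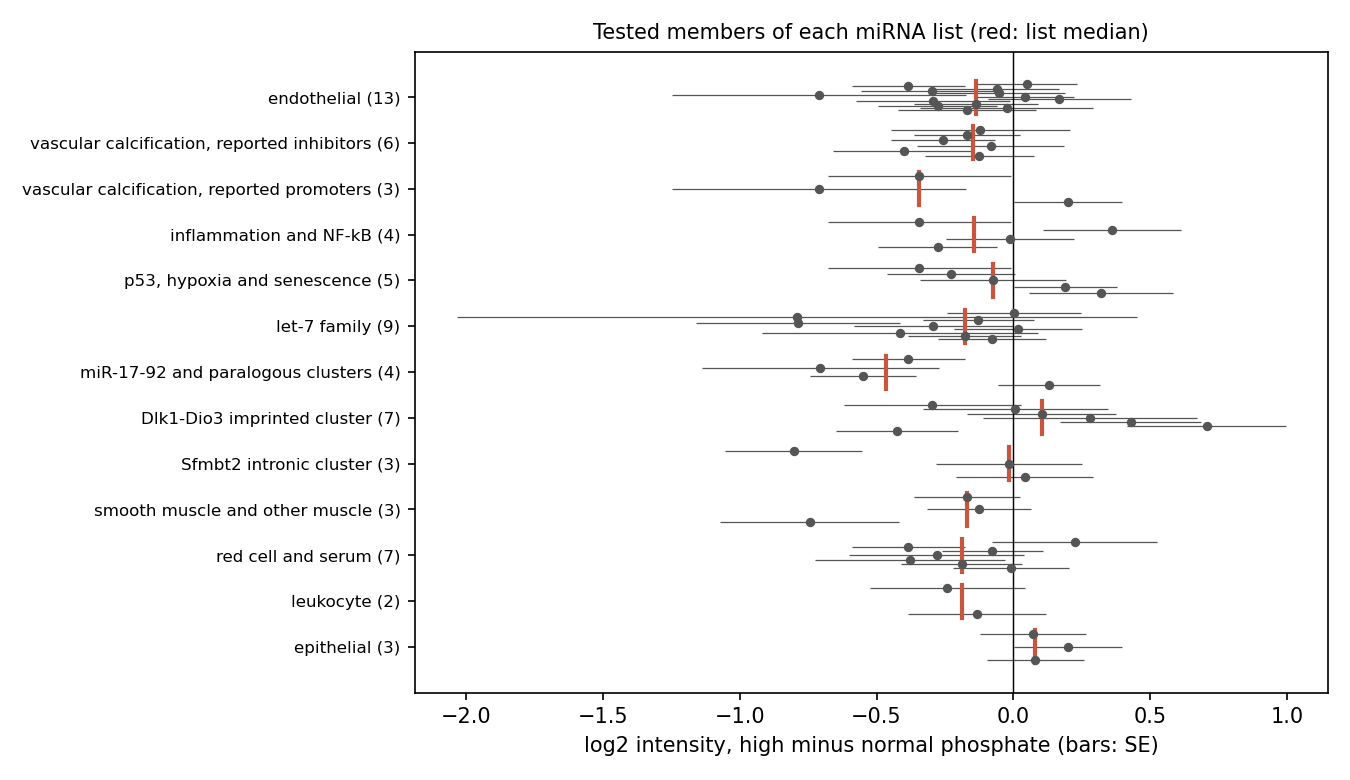
Log2 difference, high minus normal phosphate (horizontal axis), of each tested member of 13 miRNA lists, with bars for the SE, a red line at the list median and the number of tested members in brackets. The medians run from -0.47 for the miR-17-92 and paralogous clusters to 0.10 for the Dlk1-Dio3 imprinted cluster, and no list passed after adjustment.

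Arrays of the same group resembled each other about as much as arrays of different groups. The mean Pearson correlation over the 129 tested probes was 0.875 within groups (range 0.826 to 0.913) and 0.872 between groups (range 0.781 to 0.920), and 6 of the 10 possible splits into 3 and 3 arrays, the real one included, gave a difference at least as large. These correlations are across probes, which are not independent replicates. Brightness before scaling did separate the groups, for the control spots and for the mean log2 signal of the tested miRNA probes. The mean log2 signal of 47 spike control probes was 10.33 ± 0.16 (SD, n = 3) in normal and 9.67 ± 0.26 (SD, n = 3) in high phosphate, and the Hy3 spots stood at 9.35 ± 0.15 and 8.75 ± 0.19 (SD, n = 3), each with a 2-sided exact permutation p of 0.1, the smallest possible. The mean log2 signal of the tested miRNA probes before scaling was 12.70 ± 0.07 (SD, n = 3) in normal and 12.53 ± 0.11 (SD, n = 3) in high phosphate. Its arrays did not overlap either (2-sided exact permutation p = 0.1). Without scaling, the median log2 difference of the 129 miRNA probes was -0.22, and scaling to the spike controls moved it to 0.45 and to the Hy3 spots to 0.39. All differences above are therefore relative to the common level of the miRNA probes, and with either control scaling the medians of the endothelial, let-7 and calcification lists turn positive.

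**Figure D3:**
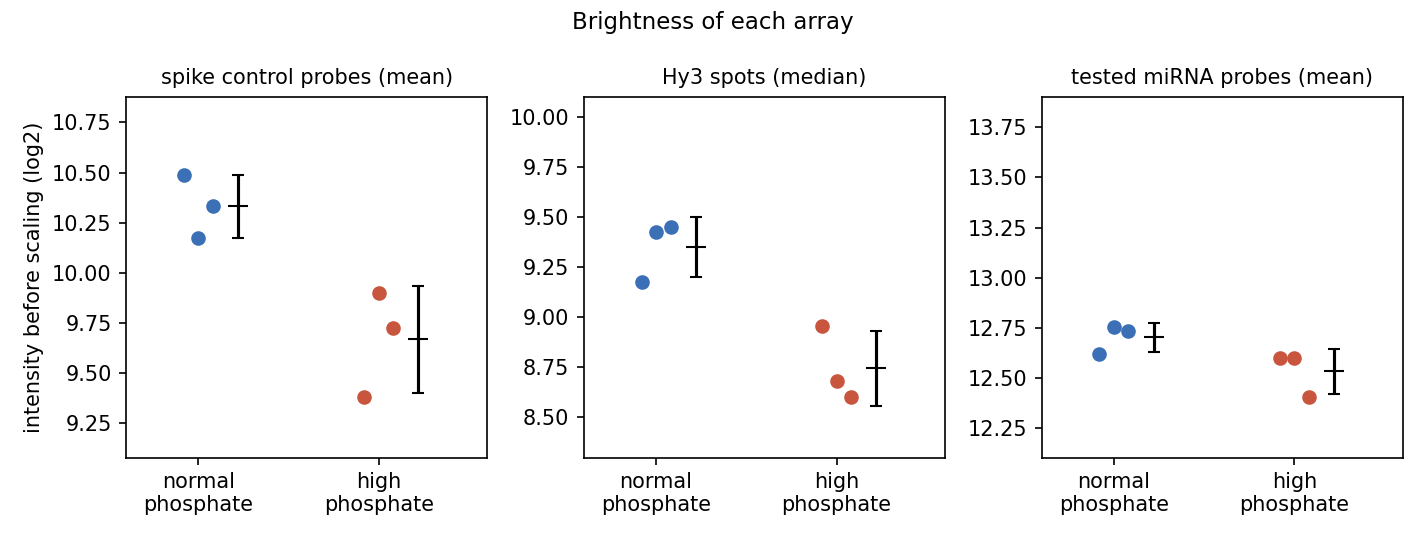
Log2 intensity before scaling (vertical axis, the same span in each panel) of the spike control probes, the Hy3 spots and the tested miRNA probes on each array, with points for the 3 arrays of a group and bars for the mean and SD. The spike controls differ by -0.66 and the Hy3 spots by -0.60 between the group means, and the tested miRNA probes by -0.17.

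The authors' deposited table gave 39 of 1029 probes with a p under 0.05, where 51.5 are expected by chance, of which 25 also reached a fold of 1.5 in either direction, 18 higher and 7 lower in high phosphate. The lowest false discovery rate in the authors' deposited table was 0.794. Of the 39, 7 were among the 129 probes tested above and 32 were not. In the authors' deposited table, miR-126a-3p had a fold of 0.629 (p = 0.0336), miR-19b-3p 0.644 (p = 0.0114), miR-466i-5p 0.528 (p = 0.0263), miR-1957a 1.58 (p = 0.0488) and miR-670-3p 1.59 (p = 0.0499).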

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

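The comparison of viral with unnamed probes was chosen only after the signals were seen, and no biological explanation was tested for the signals given here. Probes outside the mouse miRNAs gave signal above the Empty spots. The probe for mghv-miR-M1-10-3p, a miRNA of murine gammaherpesvirus, averaged 11456 units over the 6 arrays (8628 to 17426), and mghv-miR-M1-8-5p averaged 4851 units (3356 to 7100). Of 57 viral probes, 9 exceeded 1000 units (15.8%), against 265 of 2276 unnamed probes (11.6%), with an odds ratio of 1.42 (95% interval 0.607 to 2.97, Fisher's exact p = 0.302). The targets of the unnamed probes are not given in the sources used here, so this comparison does not show what the viral probes bound. The median was 159 units over the 28 probes of murine gammaherpesvirus and 3.5 units over the 29 of murine cytomegalovirus. Because the brighter viral probes set the threshold, it left out mouse probes far above the Empty spots: between 893 and 1010 mouse probes per array exceeded the 99th percentile of the Empty spots. A negative control probe, hsa_negative_control_3, averaged 1128 units (689 to 1440). Of the unnamed probes, 1831 lay above the Empty spots on at least 3 arrays.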

How the results depend on the processing

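Control scaling, the Empty-spot threshold and median scaling without a filter were chosen after seeing the data; the other alternatives were fixed before. In none of the alternatives fixed before did a mouse probe pass limma with Benjamini-Hochberg adjustment; their lowest adjusted p ran from 0.0665 without normal phosphate replicate 2 to 0.901 without normal phosphate replicate 3. Of 1345 values of named probes under alternatives, 1238 kept their direction and their side of the threshold. The count at an unadjusted p under 0.05 was 63 of 1118 probes without a filter, 42 of 684 at a mean of at least 50 units and 57 of 980 above the Empty spots, as wider filters test more probes. Median scaling with no filter, which changes the normalization as well, gave 62 of 1118. It was 5 with the equal-variance t-test, 20 with spike control scaling and 26 with Hy3 spot scaling, and ran from 5 to 14 when each array was left out in turn (5 without normal phosphate replicate 1 or 3, 14 without normal phosphate replicate 2). Counts after adjustment were 4, all higher, with Hy3 spot scaling and 5, all higher, with median scaling and no filter. The difference in probes above background per array moved from 8 to 30.3 at a fixed 50 units and to 48.7 above the Empty spots. The choice of threshold limits what was tested, since 989 mouse probes did not exceed the viral threshold on at least 3 arrays, whereas 980 mouse probes were tested above the Empty spots.

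Lists passed camera only under wider filters, and each call was lost with an estimated correlation. Without a filter these were the calcification inhibitors (-0.20, adjusted p = 0.0271), the miR-17-92 list (-0.25, adjusted p = 0.00699), the Sfmbt2 list, which turned positive (0.0405, adjusted p = 0.0329), and the leukocyte list, untested before (-0.20, adjusted p = 0.0329). The adjusted p with an estimated correlation ranged from 0.376 to 0.537 for these. At a mean of at least 50 units the miR-17-92 list stood at -0.41. Above the Empty spots the calcification inhibitors stood at -0.20, the miR-17-92 list at -0.29, the Sfmbt2 list at 0.0562 and the leukocyte list at -0.20 (adjusted p = 0.0460, and 0.369 with an estimated correlation), and with median scaling and no filter the let-7 list at -0.21, the miR-17-92 list at -0.14 and the Sfmbt2 list at 0.23.

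Differences that had not passed the test changed sign as follows, and the cause was not tested. Median scaling turned the direction to -0.20 for miR-10b-5p, 0.14 for miR-466f, 0.00346 for miR-181a-5p, -0.00996 for miR-183-5p, 0.0571 for miR-670-5p and 0.14 for the Sfmbt2 intronic cluster list. Cyclic loess turned it to -0.10 for miR-10b-5p, 0.00848 for miR-30c-5p, 0.0314 for miR-466f, 0.0117 for miR-670-5p and 0.0314 for the Sfmbt2 intronic cluster list. Without normalization between arrays it became -0.44 for miR-10b-5p, -0.16 for miR-182-5p, -0.21 for miR-192-5p, -0.22 for let-7a-5p, -0.11 for miR-25-3p, -0.0471 for miR-669n, -0.25 for miR-183-5p, -0.0847 for miR-126a-5p and -0.16 for the epithelial list. The deposited values, and identically the series value table, gave -0.42 for miR-10b-5p, -0.18 for miR-182-5p, -0.21 for miR-192-5p, -0.23 for let-7a-5p, -0.0934 for miR-25-3p, -0.11 for miR-669n, -0.22 for miR-183-5p, -0.0815 for miR-126a-5p and -0.18 for the epithelial list. Array weights gave -0.0726 for let-7a-5p and 0.044 for the p53, hypoxia and senescence list. Median scaling with no filter gave -0.20 for miR-10b-5p, 0.14 for miR-466f, 0.00346 for miR-181a-5p, -0.00996 for miR-183-5p, 0.0571 for miR-670-5p, 0.23 for the Sfmbt2 intronic cluster list and -0.11 for the epithelial list. Without a filter the median was 0.0405 for the Sfmbt2 intronic cluster list and -0.23 for the epithelial list. At a mean of at least 50 units it was 0.0841 for the Sfmbt2 intronic cluster list and -0.33 for the epithelial list. Above the Empty spots it was 0.0562 for the Sfmbt2 intronic cluster list and -0.23 for the epithelial list. Spike control scaling turned list medians positive, to 0.26 for the endothelial list, 0.29 for the calcification inhibitors, 0.0877 for the calcification promoters, 0.26 for the inflammation and NF-kB list, 0.26 for the p53, hypoxia and senescence list, 0.22 for the let-7 family list, 0.0731 for the miR-17-92 and paralogous clusters list, 0.57 for the Sfmbt2 intronic cluster list, 0.21 for the smooth muscle and other muscle list and 0.29 for the red cell and serum list. Among named probes, spike control scaling gave 0.0681 for miR-19b-3p, 0.0619 for miR-299a-5p, 0.078 for miR-92a-3p, 0.15 for miR-10a-5p, 0.0774 for miR-211-5p, 0.32 for miR-29a-3p, 0.21 for miR-143-3p, 0.38 for miR-30c-5p, 0.0877 for miR-146a-5p, 0.36 for miR-146b-5p and 0.12 for miR-215-5p. It also gave 0.12 for let-7i-5p, 0.34 for let-7g-5p, 0.57 for miR-466f, 0.34 for miR-206-3p, 0.0122 for miR-122-5p, 0.29 for miR-451a, 0.067 for miR-16-5p, 0.33 for miR-142a-5p, 0.43 for miR-181a-5p, 0.49 for miR-670-5p and 0.0871 for miR-126a-3p. Hy3 spot scaling turned list medians positive, to 0.20 for the endothelial list, 0.23 for the calcification inhibitors, 0.029 for the calcification promoters, 0.20 for the inflammation and NF-kB list, 0.20 for the p53, hypoxia and senescence list, 0.16 for the let-7 family list, 0.0143 for the miR-17-92 and paralogous clusters list, 0.51 for the Sfmbt2 intronic cluster list, 0.15 for the smooth muscle and other muscle list and 0.23 for the red cell and serum list. Among named probes, Hy3 spot scaling gave 0.00938 for miR-19b-3p, 0.00318 for miR-299a-5p, 0.0193 for miR-92a-3p, 0.0894 for miR-10a-5p, 0.0187 for miR-211-5p, 0.26 for miR-29a-3p, 0.15 for miR-143-3p, 0.32 for miR-30c-5p, 0.029 for miR-146a-5p, 0.31 for miR-146b-5p and 0.063 for miR-215-5p. It also gave 0.0644 for let-7i-5p, 0.29 for let-7g-5p, 0.51 for miR-466f, 0.28 for miR-206-3p, 0.23 for miR-451a, 0.00828 for miR-16-5p, 0.27 for miR-142a-5p, 0.37 for miR-181a-5p, 0.43 for miR-670-5p and 0.0283 for miR-126a-3p.

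Leaving out each array in turn gave both signs, with log2 differences from -0.087 to 0.21 for the Dlk1-Dio3 imprinted cluster list, from -0.24 to 0.17 for the Sfmbt2 intronic cluster list, from -0.23 to 0.15 for the p53, hypoxia and senescence list, from -0.18 to 0.14 for let-7a-5p, from -0.0517 to 0.30 for miR-126a-5p, from -0.16 to 0.13 for miR-146b-5p. They also ran from -0.47 to 0.0579 for miR-16-5p, from -0.35 to 0.0572 for miR-181a-5p, from -0.24 to 0.17 for miR-466f, from -0.0639 to 0.25 for miR-669n, from -0.29 to 0.20 for miR-670-5p.

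The replicate number as a block gave 0 calls after adjustment and 8 at an unadjusted p under 0.05, and changed no call. The main fit had no replicate block, a choice fixed beforehand. Deviations of arrays with the same number correlated at 0.22, 0.0267 and -0.18, and those with different numbers between -0.36 and 0.45. So few values cannot show whether the numbers pair the samples.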

Other observations

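The tests of the spike controls, the comparison of the other small RNAs and the counts over other splits of the arrays were chosen or run only after the results were seen. Other small RNAs than miRNAs were also measured, and their values are given without scaling. The U5 spliceosomal RNA probe (RNU5) measured 361 ± 241 units (SD, n = 3) in normal and 77.5 ± 16.4 units (SD, n = 3) in high phosphate, and a U6 probe (RNU6-1) 390 ± 126 and 165 ± 35.7 units (SD, n = 3). The nucleolar RNA SNORD68 measured 1235 ± 137 and 938 ± 137 units (SD, n = 3). In these 3 of 15 small RNA probes over 100 units every high phosphate array lay below every normal one, and 0 of 15 showed the opposite order, where chance gives 1.5 without overlap in either direction (2-sided exact permutation p = 0.1 for each of the 3, the smallest possible). After background correction, on the log2 scale, every high phosphate array lay below every normal one for 5 of the 15, also for the U1 spliceosomal RNA probe (RNU1) at -1.26 and SNORD2 at -0.21 (2-sided exact permutation p = 0.1 for each), and 0 showed the opposite order. Before it the groups overlapped for SNORD2 and for RNU1, at 584 ± 319 and 211 ± 89 units (SD, n = 3). The correction removed that overlap by raising normal phosphate replicate 2. RNU1 there went from 269 units, below high phosphate replicate 2 at 288, to a log2 level of 8.57 against 8.44. The near-blank hsa_negative_control_4 also stood at -0.37 after correction, though its units were not lower in high phosphate, while the brighter hsa_negative_control_3 stood at 0.03. The rise from 3 to 5 therefore adds no evidence. On the log2 scale the first 3 differed by -1.58 (RNU5), -1.06 (RNU6-1) and -0.41 (SNORD68), on arrays whose Hy3 spots differed by -0.60 and spike controls by -0.66, so SNORD68 and SNORD2 differed by less than the control spots. A second U6 probe (RNU6-1_RNU6-2) overlapped, at 1217 ± 356 and 1057 ± 317 units (SD, n = 3), as did 5S ribosomal RNA at 6438 ± 1048 and 6080 ± 2666 units (SD, n = 3).

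The spike control probes are taken to report RNA added in equal amount to each sample, which no source used here states, and the readings of their differences rest on it. They were dimmer on all 3 high phosphate arrays, by -0.66 on the log2 scale, and 44 of 47 bright spike probes had a lower mean there. The shift was uneven between these probes, with an interquartile range from -0.96 to -0.34, so their mean is an uncertain measure of an equal addition. These values are after background correction, which put the near-blank hsa_negative_control_4 at -0.37. The dim spike_control_v2_30 counted as lower, at -0.11, though it measured 155 ± 23 units (SD, n = 3) in normal and 161 ± 56 in high phosphate. The brightest, spike_control_v2_23, was lower in units too, at 12830 ± 3670 and 7398 ± 1152 (SD, n = 3). Lower brightness of the whole array, as the only cause, would have dimmed the miRNA probes alike, if dimming is equal at all intensities. Relative to the tested probes the spike controls still differed by -0.49, with no overlap between groups (2-sided exact permutation p = 0.1, the smallest possible). Those probes were brighter than the spike controls, with mean log2 signals of 12.70 and 10.33 in normal phosphate. Dimming that varies with intensity was not tested. More small RNA per spike control, as the only cause, would have left the Hy3 spots alike, if these hold printed dye as their name implies. The Hy3 spots differed by -0.60 (2-sided exact permutation p = 0.1, the smallest possible). With 3 against 3 arrays neither comparison can exclude chance, so neither cause is ruled out. Both causes together, or a difference in labelling or handling that coincided with the groups, could account for the pattern and stay open. So do chance and an effect of phosphate on the amount of small RNA in the vesicles. Scaling to the spike controls gave 0 calls with limma after adjustment and 20 at an unadjusted p under 0.05, and scaling to the Hy3 spots gave 4 and 26.

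The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For probes with an adjusted p under 0.05 the real count was 0, which all 10 splits reach by construction, so this count tests nothing; the highest other split gave 1. For an unadjusted p under 0.05, 4 splits, the real one included, reached the real count of 9, and the highest other gave 18. For lists with an unadjusted camera p under 0.05, 6 splits, the real one included, reached the real count of 1, and the highest other gave 2.

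Below the threshold, miR-200c-3p had the lowest p in the authors' deposited table, with a fold of 0.708 (p = 0.000808, false discovery rate 0.794). With a filter of at least 50 units in the mean, miR-670-3p had a log2 difference of 0.55 (SE 0.24, limma Benjamini-Hochberg adjusted p = 0.678).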
